A study of Homo sapiens with 3 samples.

How the data were processed

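Gene expression was measured on Affymetrix arrays in LNCaP cells, an established human prostate cancer line that expresses the androgen receptor and responds to androgen. Per the labels' protocols, the cells were kept in phenol red-free medium with serum and were transfected by lipid carrier with 75 nM of a control siRNA or of 1 of 2 siRNAs against the long non-coding RNA HOXD-AS1. RNA was taken after 48 h, amplified to biotin-tagged cRNA, fragmented and hybridised. Each of the 3 groups, control siRNA, HOXD-AS1 siRNA 1 and HOXD-AS1 siRNA 2, held 1 array. Groups were taken from the siRNA and title labels. The source labels gave 3 different names, LNCaP, LNCaP-Bic and LNCaP-AI, while the cell line label gave LNCaP for all arrays, so any difference between cells of these names could not be separated from a difference between siRNAs.

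The deposited values were probe set intensities on a linear scale, 1 column per array, in a single table of 49388 probe sets. Per the submitters' processing notes, GCOS 1.4 was used, while the background correction, summarisation and normalization steps were not given in the sources used here. The intensity distributions of the 3 deposited columns were nearly alike. The sorted log2 values of any pair of arrays differed by at most 0.10, which left little to rescale, and no further normalization was applied in the main analysis. If the arrays were brought to a common distribution before deposit, which the sources used here do not state, a shift of most transcripts in one direction would not be seen in these values.

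Intensities were put on the log2 scale. A floor was set at the median of all values over the 3 arrays, an intensity of 26.0, and lower values were raised to it. A gene counted as measured where at least 1 array was above the floor. A fold against a value at the floor is a lower bound. Gene symbols came from the platform annotation and were checked against RefSeq through the Entrez gene identifier, which matched 44961 of the 44988 probe sets with 1 gene and updated 0 symbols. A further 1831 probe sets carried several genes and 2569 were not listed, of which 102 were array controls. Probe sets with several symbols or none were given no gene name. A gene was represented by the probe set with the highest mean log2 intensity among those with 1 symbol, which gave 18131 genes, of which 11286 were measured. The annotation used here gave 0 probe sets to HAGLR, the current symbol of HOXD-AS1, so the level of the targeted transcript was not analysed here.

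With 1 array per group no siRNA could be tested against the control by itself, and the number of arrays limits the precision of every value. Genes were counted at a log2 difference of 1, a 2-fold difference, from the control in each siRNA library, in the same direction in both, and between the siRNA libraries. Each array was also taken in turn as the one that stood apart, by counting genes 2-fold or more from both other arrays in the same direction. Both siRNA differences share the control array. The Pearson correlation, the covariance and the shared counts were therefore set beside 100 simulated sets of 3 unchanged arrays with 1 common control, with noise taken from the difference between the siRNA libraries in 10 bins of expression. That noise contains any real difference between the siRNA libraries and is taken as equal in all 3 arrays. Its values were drawn for each gene separately and given random signs. Simulated higher and lower counts are therefore balanced by construction, and genes that move together are left out. Shared counts were also set beside the overlap of independent lists.

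A set of 24 gene lists with 509 different genes, of which 461 had a probe set and 388 were measured, described gene groups. The lists were mitosis and G2/M, DNA replication and G1/S, study target genes, androgen receptor-induced genes, androgen receptor-repressed genes, HOXD cluster and neighbours, WDR5 and H3K4 methyltransferase complexes, p53 target genes, apoptosis regulators, interferon response, integrated stress and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, inflammatory NF-kB targets, drug efflux and drug resistance, ribosomal proteins, the mitochondrial respiratory chain, luminal, basal and neuroendocrine markers, stromal and mesenchymal markers, leukocyte markers, markers of androgen receptor-negative prostate lines, and housekeeping genes. The median log2 difference of each list was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. The rank is a description of these libraries. Random lists hold unrelated genes, so the percentiles leave out any tendency of the genes of a list to move together. A list is described as outside the random lists where its median lay below the 2.5th or above the 97.5th percentile. The lists, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined.

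The rule named WDR5, which a label tag mentions, and the 10 genes highest and the 10 lowest in both siRNA libraries, ranked by the smaller of their log2 differences. It also named the 5 genes highest and the 5 lowest in siRNA 1 against siRNA 2, the 5 study target genes, and from each list the 2 members with the highest and the 2 with the lowest mean difference, or up to 6 each way in lists of over 20 measured members outside the random lists. Only 9 genes were 2-fold or more lower in both libraries, so 9 are named there. Genes named outside this rule are marked as chosen after their values were seen.

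The counting and list steps were tested on simulated data for the comparison of both siRNAs with the control. Among 11286 simulated genes, 200 were changed, all taken from genes well above the floor. Of these, 99% of those changed by a log2 of 2 and 93% of those changed by a log2 of 1.5 were recovered. Recovery of genes near the floor was not tried. In the same simulation 47 unchanged genes also passed, and 2 of 40 unchanged lists fell outside the central 95%. The alternatives were centring each array on its median, quantile normalization, cyclic loess, floors at the 25th and 75th percentiles, no floor and the mean of all probe sets of a gene. Another kept only plain probe sets, which left out every name ending in _a_at, _s_at or _x_at. The others were thresholds of 1.5-fold and 3-fold, list means in place of medians and unmatched random lists. In the last, limma took both siRNA arrays as replicates of a single knockdown group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, with R 4.3.3 and limma 3.58.1. A search for siRNA seed matches in transcripts and the genomic positions of the genes were not analysed here, since no transcript or genome sequence was used.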

Results

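Transcript levels were compared between LNCaP prostate cancer cells transfected with a control siRNA and cells transfected with either of 2 siRNAs against HOXD-AS1, a long non-coding RNA transcribed antisense within the HOXD gene cluster. The series sought genes whose expression differed from the control with both siRNAs, as putative targets of HOXD-AS1. Each group held 1 array, so no difference reported here has a replicate check. The control siRNA had the sequence UUCUCCGAACGUGUCACGUTT, siRNA 1 the sequence GAAAGAAGGACCAAAGUAAUU and siRNA 2 the sequence GCCCUUUCUGACCUGCUUAUU. The arrays were closely matched in signal. The median intensity was 26.1 in the control library, 25.7 with siRNA 1 and 26.1 with siRNA 2, and the highest was 18396, 18839 and 18633. Between 49.9% and 50.1% of the 49388 probe sets on each array were above the floor, which follows from setting the floor at the median of all values. Over all probe sets, the Pearson correlation of log2 intensities, which is across probe sets of the arrays and not across samples, was 0.990 between the control and siRNA 1, 0.992 between the control and siRNA 2 and 0.991 between the siRNAs.

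The knockdown itself could not be read from these arrays, because no probe set used here was annotated to HOXD-AS1. The labels give an inhibition rate relative to the control of 0.23 for siRNA 1 and 0.25 for siRNA 2, with 1 for the control, and do not say how it was measured or whether it is the level that remained or the reduction. The label for the siRNA target position, 588 and 1290, refers to the coding sequence of WDR5, a core subunit of the histone H3K4 methyltransferase complexes. The siRNA and title labels name HOXD-AS1, so what these positions refer to is unclear. WDR5 had 2 probe sets. The first read 420 in the control library, 380 with siRNA 1 and 374 with siRNA 2, log2 differences of -0.14 and -0.17, and the other read 444.5, 351.1 and 407.1, differences of -0.34 and -0.13. WDR5 mRNA was therefore within 1.5-fold of the control in both siRNA libraries. The list of 19 measured genes of WDR5 and the H3K4 methyltransferase complexes had median differences of 0.04 with siRNA 1 and 0.08 with siRNA 2, at the 60.6th and 74.6th percentiles of random lists. KMT2C was the highest of them (0.67 and 0.55), while MEN1 was among the lowest (-0.40 and -0.19). Of the HOXD cluster and its neighbours 3 genes were measured, with medians of -0.30 and -0.14, inside the random lists in both libraries. MTX2, which lies beside the cluster, differed by -0.30 and -0.35.

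Genes of mitosis and of DNA replication were lower than in the control with both siRNAs, and lower with siRNA 1 than with siRNA 2. Among 42 measured mitosis and G2/M genes, 41 were lower in both siRNA libraries, and 36 were at least 2-fold lower with siRNA 1 against 2 with siRNA 2. CDC20, an activator of the anaphase-promoting complex, was 4.07-fold lower with siRNA 1 and 2.09-fold lower with siRNA 2, although its other probe set differed less (-1.14 and -0.48 on the log2 scale). The mitotic kinesin gene KIF14 was 3.31-fold and 2.48-fold lower. CDCA8, a subunit of the chromosomal passenger complex, differed by -1.83 and -0.95 on the log2 scale, and the kinesin KIF20A by -1.74 and -0.88. The list median was -1.28 with siRNA 1 and -0.56 with siRNA 2, below all 10000 random lists in each library. With only plain probe sets, which left 7 of these genes, the siRNA 2 median was -0.34, still outside the random lists. Of 42 DNA replication and G1/S genes, 39 were lower in both libraries, with 25 at least 2-fold lower with siRNA 1 and 1 with siRNA 2. The thymidine kinase gene TK1 differed by -1.73 and -0.36, the polymerase subunit gene POLE2 by -1.75 and -0.46, the helicase gene MCM2 by -1.44 and -0.51 (-1.66 to -0.63 and -0.57 to -0.22 in 3 other probe sets), and the replication initiation gene MCM10 by -1.46 and -0.73. RRM2, which encodes the small subunit of ribonucleotide reductase, was 2.39-fold lower with siRNA 1 and 2.04-fold lower with siRNA 2. The G1 cyclin genes differed among themselves. CCNE1 differed by 0.23 and 0.37 (0.04 and 0.10 in its other probe set), and CCNE2, singled out after its values were seen, by -0.70 and -0.73. CCND1 differed by 0.42 and 0.16, but its 3 other probe sets by 0.07 to 0.28 with siRNA 1 and -0.12 to -0.09 with siRNA 2. The median of the replication list was -1.07 with siRNA 1 and -0.44 with siRNA 2, again below all 10000 random lists in each library. For comparison, 32.1% of all 11286 measured genes were lower in both siRNA libraries and 34.3% were higher in both.

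The 5 genes that the study took forward were all lower with both siRNAs and 2-fold or more lower with siRNA 1 alone. AURKA, a mitotic kinase, read 1501 in the control, 511 with siRNA 1 and 938 with siRNA 2. PLK1, another mitotic kinase, read 102, 38.4 and 65.3, and FOXM1, a transcription factor that drives mitotic genes, read 237, 86.4 and 139, with its 2 other probe sets at log2 differences of -1.46 to -0.54 with siRNA 1 and -0.68 to -0.54 with siRNA 2. The phosphatase gene CDC25C differed by -1.15 and -0.58, and UBE2C, which encodes a ubiquitin-conjugating enzyme of the anaphase-promoting complex, was 2.33-fold and 1.47-fold lower. Their median was -1.42 with siRNA 1 and -0.65 with siRNA 2. The study chose these genes on the same samples and all 5 are also members of the mitosis list, so they are not independent evidence of its direction. Without them, an alternative added after the data were seen, the median of the 37 other mitosis genes was -1.27 with siRNA 1 and -0.54 with siRNA 2.

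At the 2-fold threshold 36 genes were higher than the control in both siRNA libraries. By the probe set used for each gene, the largest shared difference was that of IL1RN, which encodes the interleukin-1 receptor antagonist, with an intensity of 55.0 in the control, 536 with siRNA 1 and 357 with siRNA 2, or 9.75-fold and 6.49-fold higher. The other IL1RN probe set differed less, by 1.80 and 1.07 on the log2 scale. TMEFF2, a transmembrane protein gene expressed in prostate epithelium, was 4.40-fold and 4.71-fold higher from a control intensity of 682, and its other probe set differed by 2.20 and 2.24. GRIN3A, a glutamate receptor subunit gene, was 4.63-fold and 4.67-fold higher. Its control intensity of 31.1 was close to the floor, and it had no other measured probe set. The fibrillar collagen gene COL5A2 was 4.34-fold and 5.00-fold higher. The 2 other COL5A2 probe sets differed less, by log2 differences of 0.91 to 1.26 with siRNA 1 and 1.31 to 1.34 with siRNA 2. CAMK2N1, which encodes an inhibitor of the kinase CaMKII, was 4.44-fold and 2.69-fold higher. CEL, SYTL2, MANEA, PEG3 and TULP4 completed the 10 highest, with log2 differences between 1.43 and 2.02. Of the 36 genes, 25 had further measured probe sets, and in 20 of these every further probe set was higher in both libraries, by a log2 of at least 0.5 in 14. Among all genes named by the rule with a log2 difference of 0.5 or more and further probe sets, every further probe set showed at least 50% of that difference in 36 of 55 with siRNA 1 and 32 of 46 with siRNA 2.

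Only 9 genes were at least 2-fold lower in both libraries. They were KIF14, CDC20, TROAP and RRM2, which act in cell division or nucleotide supply, together with DDIAS, CRYBG1, FZD4, HPSE and KIAA1191. DDIAS, a gene linked to survival after DNA damage, was 2.49-fold and 2.47-fold lower, TROAP, which encodes a spindle-associated protein, 3.05-fold and 2.46-fold lower (log2 differences of -1.46 to -1.15 and -1.19 to -0.37 in its 2 other probe sets), and FZD4, a Wnt receptor gene, 2.11-fold and 2.59-fold lower. CRYBG1 was 2.18-fold and 2.22-fold lower. HPSE, the heparanase gene, read 28.9 and 30.8 against 63.9 in the control, close to the floor. KIAA1191 was 2.14-fold and 2.00-fold lower, at the edge of the threshold.

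**Figure D1:**
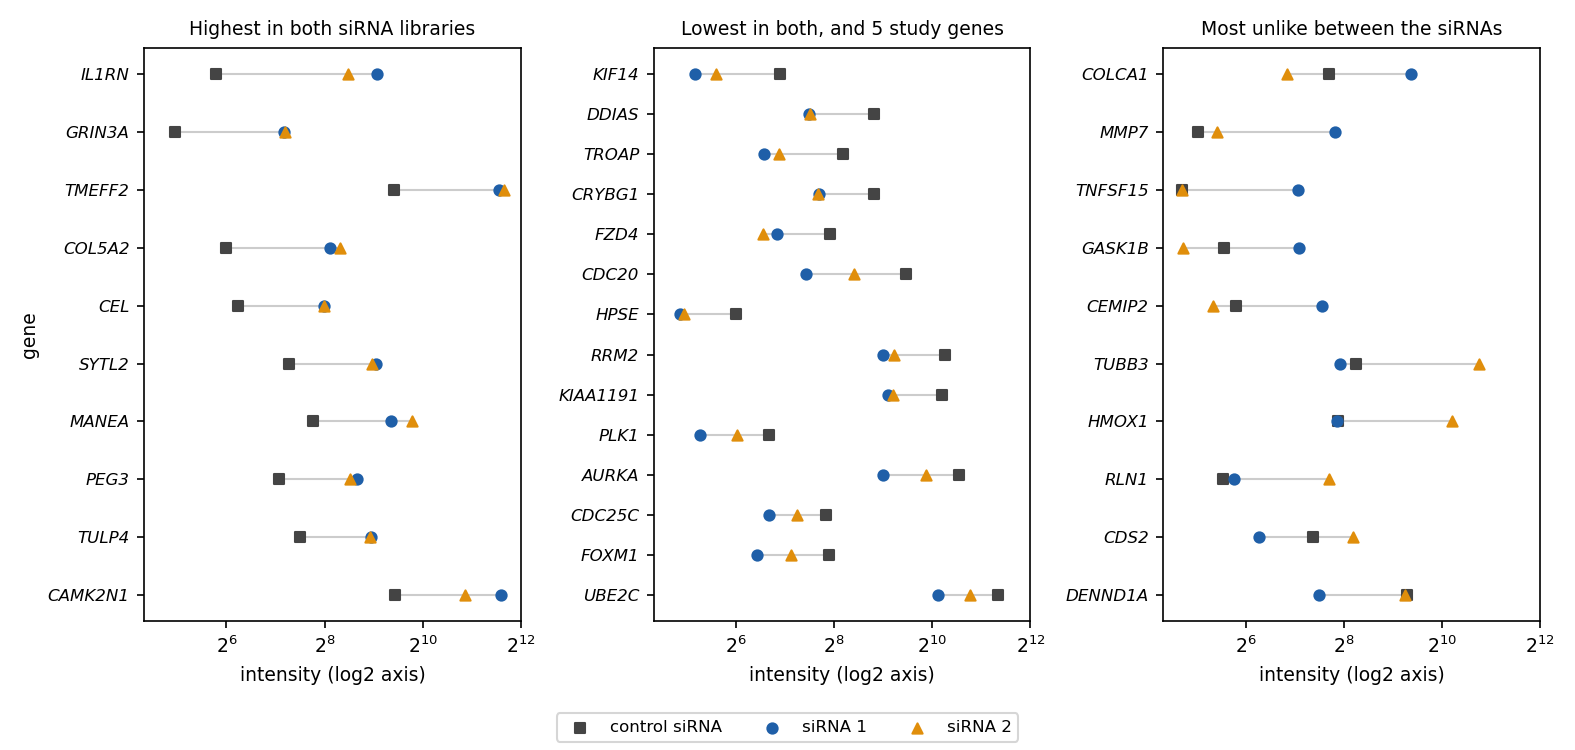
Intensities, on a log2 axis, of the genes with the largest shared differences, of the 5 study target genes and of the genes most unlike between the siRNAs, with 1 point per library and a grey line over the range. IL1RN reads 55.0 in the control against 536 and 357, AURKA 1501 against 511 and 938, and TUBB3 304 and 242 against 1733 with siRNA 2.

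The size of the shared set was set against what a common control gives by itself. Across genes, which are not independent replicates, the log2 differences of the siRNA libraries from the control correlated with r = 0.507, where unchanged arrays with 1 common control gave 0.501 on average (0.467 to 0.528 over 100 simulations). The covariance was 0.0747 against a simulated 0.0743, a difference of 0.000378. The 36 shared higher genes were above all simulated counts (mean 25, 13 to 34), and the 9 shared lower genes were below all of them (mean 25.5, 16 to 35), while the total of 45 lay within the simulated range of 34 to 69. The simulated noise had random signs and unrelated genes, so it holds no imbalance of its own and cannot test one. The imbalance of 36 higher against 9 lower also depended on the threshold, as 206 genes were higher and 172 lower in both libraries at 1.5-fold, and 7 and 0 at 3-fold. Independent lists of the 2-fold sizes would share 1.21 higher and 1.20 lower genes, a reference that leaves out the shared control. Taken in turn as the array that stood apart from both others, the control did so for 45 genes, siRNA 1 for 74 and siRNA 2 for 55. The control therefore stood apart for no more genes than either siRNA library at this threshold, whereas at 1.5-fold it did so for 378 genes against 576 for siRNA 1 and 357 for siRNA 2, and at 3-fold for 7 against 10 and 4.

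**Figure D2:**
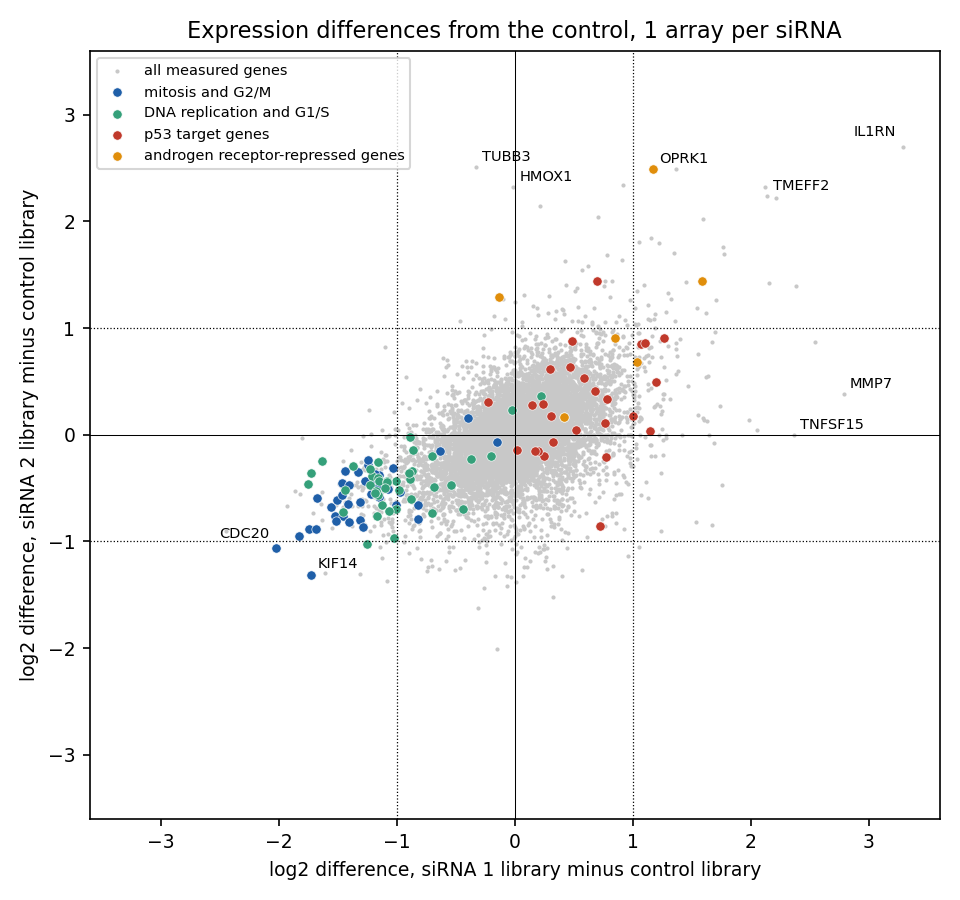
Log2 difference from the control library for each measured gene, siRNA 1 on the horizontal and siRNA 2 on the vertical axis, with 4 gene lists in colour and dotted lines at the 2-fold threshold. Mitosis and DNA replication genes gather at the lower left, with medians of -1.28 and -1.07 with siRNA 1 and of -0.56 and -0.44 with siRNA 2.

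Against the control alone, 352 genes (3.12% of those measured) were 2-fold or more different with siRNA 1, 153 higher and 199 lower. With siRNA 2 there were 157 (1.39%), 89 higher and 68 lower. The balance turned for siRNA 1 at 1.5-fold (779 higher and 695 lower), at 3-fold (29 and 19) and with only plain probe sets (56 and 48), and for siRNA 2 with only plain probe sets (28 and 33). The siRNA 1 total was above the 188 to 247 genes of simulated unchanged arrays and the siRNA 2 total below their 180 to 252, so the simulated arrays match neither count. The siRNA libraries, whose difference gave the noise, themselves differed in 250 genes, where the simulated means were 217 and 220. The simulated counts thus ran low at this threshold, and their ranges are only a rough guide.

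Targets of p53 were mostly higher with both siRNAs. Of 26 measured p53 target genes, 18 were higher in both libraries and 0 were lower in both, with 6 at least 2-fold higher with siRNA 1 and 1 with siRNA 2. CDKN1A, which encodes the cell-cycle inhibitor p21, differed by 1.07 and 0.85, SESN1 by 1.11 and 0.86, and TP53I3 by 0.70 and 1.45. The pro-apoptotic gene BBC3 differed by 1.26 and 0.91, but its other probe set by 0.14 and 0.34. The remaining 8 genes of the list went opposite ways with the siRNAs. Among them TP53INP1 was higher with siRNA 1 (0.72) and lower with siRNA 2 (-0.85). The list median was 0.55 with siRNA 1 and 0.29 with siRNA 2, above all 10000 random lists in each library. When all probe sets of a gene were averaged, the siRNA 1 median was 0.286 and stayed outside the random lists. The 17 apoptosis regulators, 3 of which are also p53 targets, had medians of 0.44 and 0.31, at the 100th and 99.9th percentiles. They included both pro- and anti-apoptotic genes. The effector caspase gene CASP6 differed by 0.64 and 0.58 and the pro-apoptotic BAD by -0.31 and -0.33. With only plain probe sets, which left 5 genes, the siRNA 1 median of the apoptosis list was 0.35 and lay inside the random lists, and with averaged probe sets the medians were 0.22 and 0.21, outside them.

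Interferon response genes were mostly higher with siRNA 1 and went both ways with siRNA 2. Among 28 measured genes, 15 were higher in both libraries and 4 lower in both, with 5 at least 2-fold higher with siRNA 1 and 2 with siRNA 2. IRF9, a subunit of the interferon-activated transcription factor complex, differed by 1.03 in each library and by 0.34 to 0.78 in its 3 other probe sets. The antiviral gene OAS1 differed by 1.11 and 0.84, with its 2 other probe sets at 0.12 to 1.03 with siRNA 1 and 0.28 to 0.49 with siRNA 2. IFIT2 differed by 1.55 with siRNA 1 and 0.18 with siRNA 2, and its other probe set by 0.18 and 0.00. HERC5 differed by 0.43 and -0.91 and IFITM3 by 0.01 and -0.61. In all, 9 genes of the list went opposite ways with the siRNAs or showed no difference in a library. The list median was 0.43 with siRNA 1, above all random lists, and 0.13 with siRNA 2, at the 95.2nd percentile. With only plain probe sets, which left 8 genes, the medians were 0.77 and 0.27, both outside the random lists. The siRNA 2 value was also outside them with the floor at the 25th percentile (0.153) and as a mean (0.150), but was 0.08 with the floor at the 75th percentile and 0.02 with averaged probe sets, inside them. The 13 inflammatory NF-kB targets had medians of 0.03 in each library, inside the random lists.

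Most of the few measured genes that the androgen receptor represses were higher with both siRNAs, while androgen receptor-induced genes went both ways. Of 12 listed repressed genes 6 were measured, and 5 of these were higher in both libraries. The 5 include CCND1 (0.42 and 0.16), whose 3 other probe sets differed by -0.12 to -0.09 with siRNA 2. The remaining gene, DDC, differed by -0.14 and 1.29. The imprinted gene PEG3 differed by 1.59 and 1.45, with its other probe set at 1.52 and 1.07. OPRK1, the kappa opioid receptor gene, differed by 1.17 and 2.49, but its 3 other probe sets by -0.13 to 0.37 with siRNA 1 and 0.76 to 2.02 with siRNA 2. The list medians were 0.94 and 1.10, above all 10000 random lists in each library. They were 0.349 and 0.455 when all probe sets of a gene were averaged and 0.42 and 0.68 without a floor, and 0.43 with siRNA 1 for the floor at the 75th percentile, all outside the random lists. Of 25 androgen receptor-induced genes, 9 were higher and 12 lower in both libraries. ACP3, which encodes prostatic acid phosphatase, differed by 1.22 and 1.80 (0.34 to 1.19 and 1.10 to 1.77 in 3 other probe sets) and the metalloreductase gene STEAP2 by 0.75 and 0.55, whereas PLPP1 differed by -0.71 and -1.18 and the prostein gene SLC45A3 by -0.91 and -0.56. KLK3, the prostate-specific antigen gene, which was singled out after its values were seen, differed by -0.16 and -0.43. The induced list had a median of 0.02 with siRNA 1, at the 57.8th percentile, and of -0.23 with siRNA 2, at the 0.09th percentile. That siRNA 2 value lay inside the random lists with the floor at the 25th percentile or no floor (-0.10 each), as a mean (-0.13) and with only plain probe sets, which left 6 genes (-0.11).

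Metabolic groups differed less. Among 25 hypoxia and glycolysis genes 15 were higher in both libraries, led by the collagen prolyl hydroxylase genes P4HA2 (1.36 and 0.86) and P4HA1 (0.71 and 0.56), with list medians of 0.19 and 0.18 at the 98.7th and 99.4th percentiles. These medians were 0.08 and 0.03, inside the random lists, when all probe sets of a gene were averaged. Also inside them were the siRNA 2 value as a mean (0.143) and the siRNA 1 median with only plain probe sets, which left 4 genes (0.276). In the mean of both siRNAs the hypoxia list was inside them under 2 alternatives. Glycolytic genes in the same list went both ways. ENO1, TPI1 and LDHA differed by -0.08 to -0.20, while GAPDH differed by 0.25 and 0.31. Of 28 mitochondrial respiratory chain genes, 15 were lower in both libraries, and the median was -0.20 with siRNA 1, at the 0.21st percentile, and -0.01 with siRNA 2. With only plain probe sets, which left 7 genes, the siRNA 1 median was -0.26 and inside the random lists. ATP5MC1, an ATP synthase subunit gene, differed by -1.64 and -0.65 and SDHD, a succinate dehydrogenase subunit gene, by -1.27 and -0.44. The 19 cholesterol synthesis genes had a median of -0.24 with siRNA 1, at the 0.38th percentile, and 0.10 with siRNA 2. EBP, a sterol isomerase gene, differed by -0.80 and -0.38, and the sterol-responsive INSIG1 by 0.38 and 0.61 (0.06 to 0.16 and 0.59 to 0.67 in its 2 other probe sets). The siRNA 1 value of this list was inside the random lists as a mean (-0.13), and only 1 of its genes was left with plain probe sets. Genes of the integrated stress and unfolded protein response had medians of 0.14 and 0.06 over 26 genes, inside the random lists, with the serine synthesis gene PHGDH at -0.92 and -0.27. ATF3 differed by 1.11 and 0.60, but its 2 other probe sets by 0.16 to 0.48 and 0.18 to 0.31. The siRNA 1 median of this list was outside the random lists with the floor at the 75th percentile (0.197) and as a mean (0.176), but was -0.02 with averaged probe sets. Ribosomal protein genes (27 measured, 0.03 and -0.07) and housekeeping genes (13 measured, 0.06 and -0.00) were inside the random lists in both libraries.

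Luminal epithelial markers had medians of 0.20 and 0.09 over 11 genes, inside the random lists in each library, and their members went both ways. SPDEF, a luminal transcription factor gene, differed by -0.47 and -0.52 and the splicing factor gene ESRP1 by -0.14 and -0.68. CDH1, the E-cadherin gene, differed by 0.69 and 0.82, but its other probe set by -0.05 and 0.10. Few markers of other lineages or lines were measured, namely 4 basal (0.08 and -0.02), 9 stromal and mesenchymal (-0.09 and 0.07), 3 neuroendocrine (-0.09 and 0.27), 4 leukocyte (0.04 and 0.31) and 4 of androgen receptor-negative prostate lines (-0.01 and 0.10). The leukocyte median with siRNA 2 was at the 97.8th percentile but lay inside the random lists under 6 alternatives, among them no floor (0.12) and the mean in place of the median (0.25). ACTA2, the smooth muscle actin gene, differed by 1.16 and 1.85, and DDC, which encodes an aromatic amino acid decarboxylase, by -0.14 and 1.29. The 9 drug efflux and drug resistance genes had medians of 0.09 and 0.17, inside the random lists, while the siRNA 2 value as a mean was 0.404, outside them. Alternatives also placed outside them the siRNA 2 means of the neuroendocrine (0.56, over 3 genes) and stromal (0.31) lists. With the floor at the 75th percentile only 1 neuroendocrine and 1 basal gene were left. The siRNA 1 median of the basal list was outside them with the floor at the 25th percentile (0.23). Over all 24 lists, 10 were outside the random lists in the mean of both siRNAs, 4 below and 6 above. By chance 1.2 would be outside, if the genes within a list were as unrelated as those of the random lists. The 4 below include the study target list, which was chosen on these samples and lies wholly within the mitosis list. It is therefore not a separate result in this count. The respiratory chain list (2.44th percentile) and the luminal list (97.7th percentile) were the nearest to the limits. The first was inside them under 7 alternatives and the second under 5. With averaged probe sets they were at the 21.1st and 71.6th percentiles, with medians of -0.11 and 0.01.

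**Figure D3:**
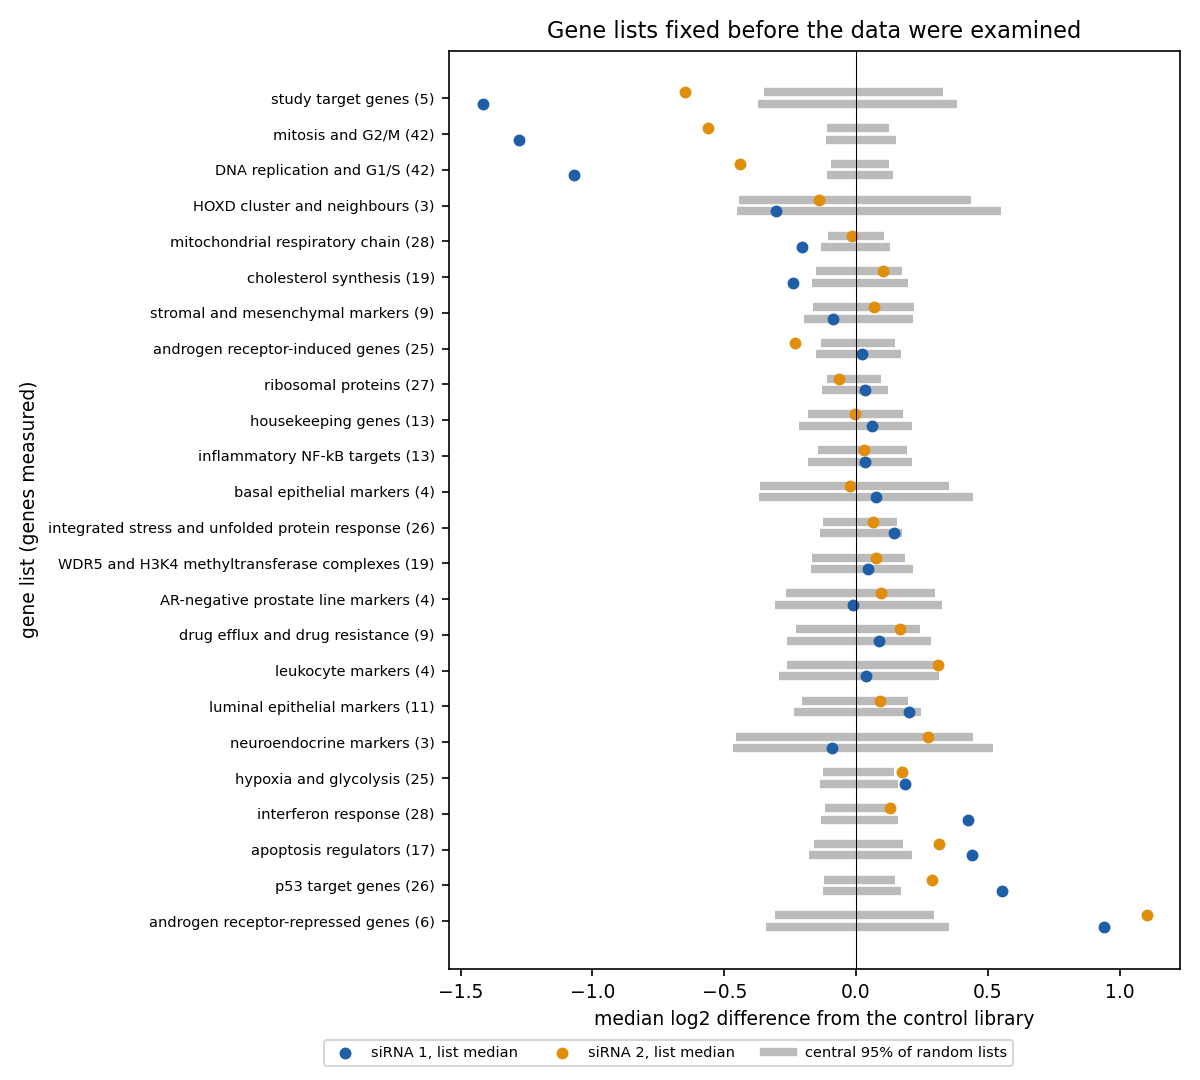
Median log2 difference from the control for the 24 gene lists, siRNA 1 in blue and siRNA 2 in orange, with the number of measured genes in parentheses and a grey bar for the central 95% of 10000 random lists. The study, mitosis and replication lists lie far to the left of their bars in both libraries, and the androgen receptor-repressed list, at 0.94 and 1.10, far to the right.

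The comparison of the siRNA libraries with each other asked how alike siRNAs against the same RNA were. They differed 2-fold or more in 250 genes (2.22%), of which 176 were higher with siRNA 1 and 74 lower. TUBB3, a neuronal beta-tubulin gene, read 1733 with siRNA 2 against 304 in the control and 242 with siRNA 1. HMOX1, which encodes the stress-induced heme oxygenase, read 1182 with siRNA 2 against 236 and 234, and the relaxin gene RLN1 read 207 against 46.7 and 54.0. Neither TUBB3, read by an _x_at probe set, nor RLN1 had another measured probe set to compare. In the other direction, MMP7, a matrix metalloproteinase gene, read 225 with siRNA 1 against 32.6 in the control and 42.5 with siRNA 2. TNFSF15, a cytokine gene, was at the floor in the other libraries and at least 5.16-fold higher with siRNA 1. CEMIP2 was 3.37-fold higher than the control with siRNA 1 and 1.39-fold lower with siRNA 2, where its 3 other probe sets differed by -0.90 to 0.00. COLCA1 and GASK1B were higher than the control with siRNA 1 (1.67 and 1.54) and lower with siRNA 2 (-0.85 and -0.82), while CDS2 was lower with siRNA 1 (-1.10) and higher with siRNA 2 (0.83). DENND1A was 3.48-fold lower than the control with siRNA 1 and near it with siRNA 2 (-0.03). The other probe set of CDS2 differed from the control by 0.20 and 0.58 and that of TNFSF15 by 0.20 and 0.00, and those of DENND1A by between -0.29 and 0.43 with siRNA 1. With siRNA 2, the other probe set of COLCA1 differed by -0.33 and those of GASK1B by -0.76 to 0.00. Among the 250 genes, 161 had further measured probe sets, which all differed in the same direction in 134, and by a log2 of 0.5 or more in 71.

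Of the 24 lists, 10 were also outside the random lists between the siRNA libraries. The 10 include the study target list, which was chosen on these samples and lies wholly within the mitosis list. All 42 mitosis genes were lower with siRNA 1 than with siRNA 2, with a median difference of -0.74, and 38 of the 42 replication genes were (median -0.56). The study target genes (-0.69), cholesterol synthesis (-0.22), respiratory chain (-0.19) and stromal (-0.31) lists were also lower with siRNA 1, and the p53 target (0.30), interferon response (0.21), luminal (0.19) and androgen receptor-induced (0.16) lists were higher. The median difference between the siRNA libraries for mitosis genes was thus larger in size than the -0.56 between siRNA 2 and the control.

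Technical readings also moved with the groups. The ratio of the 3' to the 5' control probe sets of ACTB was 17.7 in the control, 22.8 with siRNA 1 and 23.95 with siRNA 2, and that of GAPDH was 1.80, 1.85 and 2.03. The 7 background control probe sets above the floor had a median difference from the control of -0.16 with siRNA 1 and 0.01 with siRNA 2. The source labels also gave a different cell name to each array, LNCaP for the control, LNCaP-Bic for siRNA 1 and LNCaP-AI for siRNA 2, so the names coincide with the siRNAs.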

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

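The tests of explanations in this part were chosen after the results they bear on were seen. Values quoted for other floors, means or averaged probe sets come from the alternatives fixed beforehand. Several named genes lay on opposite sides of the control with the 2 siRNAs, and the difference between the siRNAs was not tested for any of them, since each library is a single array. COLCA1 was 2.52 higher on the log2 scale with siRNA 1 than with siRNA 2 (1.67 and -0.85 from the control), and GASK1B was 2.35 higher (1.54 and -0.82), while with siRNA 2 their further probe sets were between -0.76 and 0.00. CDS2 differed by -1.93 (-1.10 and 0.83), although its other probe set was above the control with both siRNAs. TP53INP1, a p53 target gene, differed by 1.57 (0.72 and -0.85). Outside the named genes, 2 of the 2014 measured probe sets that carry several gene names or none were 2-fold or more above the control in both siRNA libraries, and 1 was as far below it.

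Cell cycle genes were lower than the control with both siRNAs. A control array that alone stood apart would give both libraries about the same difference, and the mitosis median of siRNA 1 minus siRNA 2, -0.745, below all random lists, argues against this as the whole of the pattern. An offset from scaling would shift genes of the same expression alike, and it is argued against because the mitosis median, -0.56 where it was closest to 0, lay below all 10000 random lists matched on expression. A growth state that differed between the cultures for reasons other than the knockdown remains open, because the step between the siRNA libraries was 1.33 times the step from siRNA 2 to the control although both siRNAs are labelled as directed at HOXD-AS1. Knockdown of HOXD-AS1, the difference the design sets, may account for the lower values and stays open too. With 1 array per siRNA it cannot be separated from growth state or from the different cell names in the source labels.

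Of 6 measured androgen receptor-repressed genes, 5 were higher with both siRNAs. The list medians were 0.94 and 1.10, or 0.349 and 0.455 when all probe sets of a gene were averaged. Lower androgen receptor output is a candidate explanation, and it would need androgen receptor-induced genes to be lower. With siRNA 2 their median was -0.23 (-0.232), at the 0.09th percentile, which goes with it, but the median was -0.10 without a floor and -0.13 as a mean, both inside the random lists. With siRNA 1 the median was 0.0228, at the 57.8th percentile, and 9 of the 25 genes were higher in both libraries against 12 lower in both, which leaves the explanation open for that library. Cells of different origin also remain open, because the source labels carry 3 names that coincide with the siRNAs, and neither these nor the knockdown can be set aside from 1 array each.

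The siRNA libraries differed from each other in 250 genes at the 2-fold threshold. Single probe sets that misread are argued against as the main source of the direction, because in 83.2% of the genes with further measured probe sets all of these differed in the same direction. For the size they remain open, because in only 44.1% did all of these differ by a log2 of 0.5 or more, and with the mean of all probe sets of a gene the count was 105. A siRNA 2 response that was only a smaller copy of the siRNA 1 response would not by itself give genes that differ with siRNA 2 alone. In 5 genes all probe sets, at least 2 each, were 2-fold or more from the control with siRNA 2 and little different with siRNA 1. Among them was HMOX1, with further probe sets between 2.09 and 2.23 with siRNA 2. All of these probe sets read the same RNA, so a difference of that 1 culture could give such genes too. The question therefore stays open. Effects of each siRNA on other transcripts through its seed sequence could also contribute and were not analysed here. Cells of different origin remain open as well, because the source labels name LNCaP-Bic for siRNA 1 and LNCaP-AI for siRNA 2.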

How the results depend on the processing

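Tests added after the data were seen are the counts of genes with all probe sets in one direction, 40 shared by both siRNAs and 223 between them, and the mitosis list without the study target genes. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Other scalings moved no count by over 1.5 times. With the floor at the 75th percentile, 24 genes were shared by both siRNAs, 177 passed with siRNA 1, 85 with siRNA 2 and 120 between the siRNAs, and the control, siRNA 1 and siRNA 2 arrays stood apart for 24, 30 and 32 genes. With the mean of all probe sets of a gene these counts were 20, 200, 79 and 105, and 20, 30 and 27. With only plain probe sets, which left 3412 genes, they were 15, 104, 61 and 101, and 15, 33 and 25. At 1.5-fold they were 378, 1474, 1063 and 1286, and 378, 576 and 357, and at 3-fold 7, 48, 23 and 30, and 7, 10 and 4. Higher floors and the restriction to plain probe sets leave fewer genes, and the cause of the other shifts was not tested. With limma and the siRNA arrays taken as replicates, 0 genes passed an adjusted p of 0.05 (smallest 0.833), and 461 had an unadjusted p under 0.05 where 564 would by chance, with 1 residual degree of freedom. The correlation ranged from 0.462 to 0.532 and the covariance from 0.0594 to 0.0747. The number of lists outside the random lists was 5 with only plain probe sets and 7 to 10 under the other alternatives, and the cause was not tested. Over all list medians and alternatives, 669 calls were as in the main analysis, 33 were lost and 12 were gained. The sign differed for 46 medians, and 0 of these were medians that lay outside the random lists in the main analysis. The mitosis median ranged from -1.29 to -1.15 with siRNA 1 and from -0.57 to -0.34 with siRNA 2. Of the named gene values 1884 moved by less than the spread of their expression bin and 104 by more. The alternatives for the HOXD-AS1 level were not run, since no probe set used here is annotated to it. The floor was set as a percentile and not from a measured background. It limits low genes, as 11286 of 18131 genes had an array above it.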

Other observations

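The gene groups in this part, and the genes named from them, were all chosen after the data were seen, and their percentiles only describe these libraries. Replication-dependent histone genes, of which 18 of 59 listed were measured, had higher medians than the control, unlike the DNA replication list. Of 18 measured genes 12 were higher in both siRNA libraries and 4 lower in both, with medians of 0.37 with siRNA 1 and 0.70 with siRNA 2, above 9998 of the 10000 random lists with siRNA 1 and above all of them with siRNA 2. H2BC21 differed from the control by 1.04 and 1.34, H2BC5 by 0.71 and 1.43 and H2BC12 by 0.75 and 0.97, while H2AC20 differed by -0.89 and -0.20. Most transcripts of this class lack a poly(A) tail, and the part of them that these probe sets read was not analysed here. These values therefore do not show whether histone transcripts of S phase were higher.

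Groups close to the cell cycle followed the mitosis and replication lists. Of 24 centromere and augmin subunit genes 23 were lower in both libraries, with medians of -0.70 and -0.35, among them CENPM (-1.20 and -0.58), CENPW (-1.23 and -0.55) and HAUS1 (-0.78 and -0.74). Of 19 Fanconi anaemia and homologous recombination genes 18 were lower in both, with medians of -0.73 and -0.39, among them RAD54L (-1.19 and -0.48) and BLM (-1.13 and -0.53). Proteasome subunit genes differed little but in the same direction, as 23 of 27 were lower in both, with medians of -0.19 and -0.13 and PSMB3 at -0.70 and -0.52. Vacuolar ATPase subunit genes had medians of 0.03 and 0.20, the latter at the 99.1st percentile. The medians of all these groups kept their sign under the 3 other scalings of the arrays.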
